A study of Anguilla anguilla with 38 samples.

How the data were processed

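Liver RNA of 38 European eels was measured on 1-colour Agilent arrays, with 1 array per animal. Animals came from 4 sites: 8 from Lake Bolsena in Italy, 7 from the Wijmeers pond, 8 from the Hazewinkel pond and 15 from the Dessel-Schotel canal, the last 3 in Belgium. Per the series' design text, Bolsena and Wijmeers were low in pollution, Hazewinkel was highly polluted and Schotel extremely polluted. Site was taken from the sampling location given for each animal. Replicate numbers were given in order of deposit, so they name an animal and pair nothing.

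Per the labels' protocols, total RNA was extracted with a column kit, amplified and labelled with cyanine 3 by a low-input protocol. Per the series' design text, each slide was scanned at a resolution of 5 micrometres at sensitivity settings of 100% and 10%, and the scan pair was combined during feature extraction. Per the file headers, spots were quantified with Agilent Feature Extraction 9.5.1.1. The deposited scanner intensity used here was the processed signal, on a linear scale, which per the series' design text is background-subtracted and multiplicatively detrended. The authors' own value table holds a normalized intensity per array, still linear. Its values had the same order as the processed signal on each array (rank correlation 1) and a common maximum across arrays. The exact normalization behind it is not given in the sources used here. Part of its cells are empty: 10419 to 13365 of the 14913 probes had a value on an array. On each array, 257 to 682 of the probes without a value were well above background. The medians of its columns lay between 64.8 and 168. The lowest was that of Schotel 14, with the most values, and the highest that of Schotel 2, with the fewest, so the medians cover unlike sets of probes. The table served as an alternative, with empty cells as missing values.

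Each array held 15449 features, of which 14913 were non-control probes of 60 bases. Control spots were left out, and 103 spots with an outlier flag were set to missing. The log2 of the processed signal was taken and the 75th percentile of the array subtracted, so that levels are in log2 units against that percentile. Probes were tested if they were well above background on at least 70% of the arrays of at least 1 site, which kept 9628 probes. Saturation affected 3 spots over all arrays. No named probe was below background on every array of a site that it was compared in.

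The 75th percentile of the processed signal ran from 216 to 957 in Bolsena, 304 to 578 in Hazewinkel, 125 to 946 in Schotel and 309.9 to 625 in Wijmeers. Between 48.9% and 59.0% of probes were well above background on the Bolsena arrays, against 57.7% to 69.0% in Hazewinkel, 54.1% to 71.0% in Schotel and 58.3% to 67.9% in Wijmeers. The number of arrays limits the precision of every comparison. Correlations between arrays of 1 site lay between 0.896 and 0.971, so no array was a copy of another of its site. In 137 sets of tested probes with an identical sequence, the median range of levels within a set on 1 array was 0.08 log2 units, against a median SD between animals of 0.51 to 0.60.

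Comparisons used limma 3.58.1 in R 4.3.3, with lmFit and eBayes on a model of 4 site means over all 38 arrays and 34 residual degrees of freedom. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 9628 probes of a comparison, with a threshold of 0.05. The 6 pairs of sites were compared, and in a further comparison the mean of the Hazewinkel and Schotel site means was set against the mean of the Wijmeers and Bolsena site means. Each probe's difference is the first-named site minus the second. Overlaps between lists of calls were tested with Fisher's exact test, two-sided, which treats probes as independent although they are not. Figures were drawn with matplotlib 3.10.9.

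The design, the thresholds, the rule for named probes and the first set of other settings were fixed before the data were examined. Probes carry no gene name: all 14913 have the description of an unknown, and 0 of the probe names matched a symbol or accession in the RefSeq table of the assembly fAngAng1.pri. The 24 gene lists fixed for this tissue (xenobiotic metabolism, stress and other liver functions) therefore had no members to test and give no result here. Under the rule for that case, probes are named by ID: of those that passed, the 2 with the largest rise and the 2 with the largest fall in each comparison. One probe of the Schotel and Wijmeers comparison was named outside the rule, since only 4 probes passed there. Probe names begin with P, N, S or AS; what these letters stand for is not given in the sources used here. Of the probes, 442 share their sequence with another probe.

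The method was tested on simulated data, with 200 of the 9628 probes changed by a known amount on residuals of the real arrays. For a simulated change of 1 log2 unit, it recovered 40.3% of changed probes between Hazewinkel and Wijmeers, 52.1% between Schotel and Wijmeers, 50.4% between Schotel and Hazewinkel, 41.9% between Hazewinkel and Bolsena, 53.8% between Schotel and Bolsena, and 37.8% between Wijmeers and Bolsena. For a change of 2 units, the lowest share recovered was 82.0%, between Wijmeers and Bolsena. False calls among the unchanged probes averaged 23.6 per run between Schotel and Wijmeers and 0.6 to 13 in the other pairs. With no probe changed, calls averaged 0.4 per run between Schotel and Wijmeers and 0 in the other pairs, over 5 runs. So few runs can miss rare high counts. In 100 other simulations of unchanged groups, Hazewinkel and Schotel against Wijmeers shared up to 204 calls.

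Slide and scan were examined as batches. The arrays lay on 7 slides, numbered here from 1. Slides 1, 2 and 3 held only Bolsena arrays (2, 1 and 5) and were scanned apart from all Belgian arrays. Slide 4 held 6 Hazewinkel arrays and slide 5 held 8 Schotel arrays. Slide 6 held 2 Hazewinkel and 6 Schotel arrays, and slide 7 held 1 Schotel and 7 Wijmeers arrays. Slide entered as a fixed block among the Belgian arrays, which slides 6 and 7 connect, and as a random block (duplicateCorrelation, consensus correlation 0.15) elsewhere.

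The first set of other settings was quantile normalization, median centring, normexp background correction with an offset of 50, no filter on dim probes, only the 6268 probes well above background on all arrays, slide as a block, the authors' value table, only the arrays compared, array weights, a trended and robust eBayes step and leaving out each array in turn. Settings added after the data were seen were leaving out arrays whose 75th percentile was under 200, that percentile as a covariate, slide as a random block among the Belgian sites, Schotel arrays of slide 5 or 6 only, and slides 6 and 7 alone.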

Results

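Hepatic transcript levels were measured in 38 European eels, Anguilla anguilla, from 4 waters that differed in pollution, with an array of 14913 probes made for this species. Wijmeers, a pond, and Bolsena, a lake, stood for low pollution. Hazewinkel, a pond, was highly polluted, and the canal at Schotel was extremely polluted. Levels are given in log2 units against the 75th percentile of each array, with n as the number of animals. The study asked which transcripts differ in eels from polluted water. Of 9628 probes tested, the number that differed between sites ran from 4 between Schotel and Wijmeers to 2497 between Hazewinkel and Bolsena. The number did not follow the stated order of pollution: against Wijmeers, the extremely polluted site gave 4 probes and the highly polluted site 2074. No slide held both Hazewinkel and Wijmeers arrays. With slide as a fixed block, which rested on 1 Schotel array, these counts were 10 and 21. Against Bolsena, without a block, they were 2137 and 2497.

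**Figure D1:**
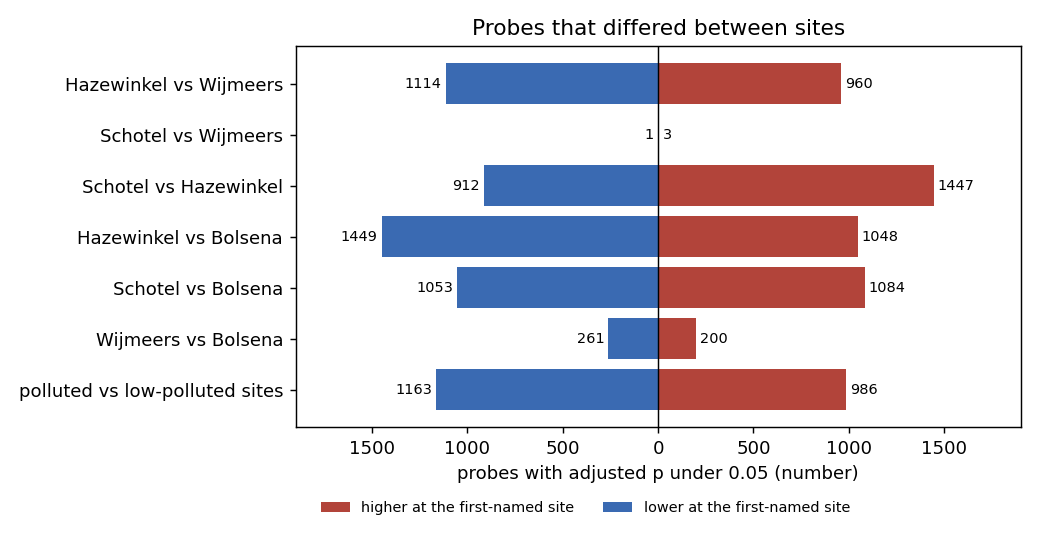
Number of probes with an adjusted p under 0.05 (horizontal axis) in each comparison (vertical axis), with probes higher at the first-named site to the right of 0 and lower ones to the left. Hazewinkel against Wijmeers gave 960 higher and 1114 lower probes, and Schotel against Wijmeers gave 3 and 1.

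Hazewinkel livers had the most probes that set 1 site apart from all others. In Hazewinkel, 401 probes were higher than at each of the other 3 sites and 469 were lower, each in 3 tests. These tests share the 8 Hazewinkel arrays and the estimate of spread, so they are not independent. Of the 8 Hazewinkel arrays, 6 lay alone on slide 4, and against Wijmeers 600 probes passed with slide as a random block and 21 with slide as a fixed block, while the 401 and 469 probes were not tested again with a block. Bolsena had 122 such higher and 68 lower probes, Schotel had 1 higher and 0 lower, and Wijmeers had 0 of either. Such a probe must pass against every other site. Schotel and Wijmeers could therefore have at most 4, the number that passed between them, and Bolsena at most 461, the number against Wijmeers. The contrast of Hazewinkel with these sites was thus largely set by those counts. In a principal component analysis, site accounted for 81.2% of the spread of the second component, which held 11.8% of the variance. All 8 Hazewinkel arrays lay at its lower end, between -65.7 and -20.6, below every other array, while the ranges of the other sites overlapped. The first component held 16.6% of the variance, and site accounted for 34.7% of its spread. Its lower end held Schotel arrays 2, 6, 7 and 15 and Hazewinkel array 1, whose 75th percentiles were 139, 156, 125, 272 and 304. Bolsena arrays 2 and 3, with 75th percentiles of 279 and 216, were dimmer than Hazewinkel array 1 and lay at 20.7 and 18.2 on that component.

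**Figure D2:**
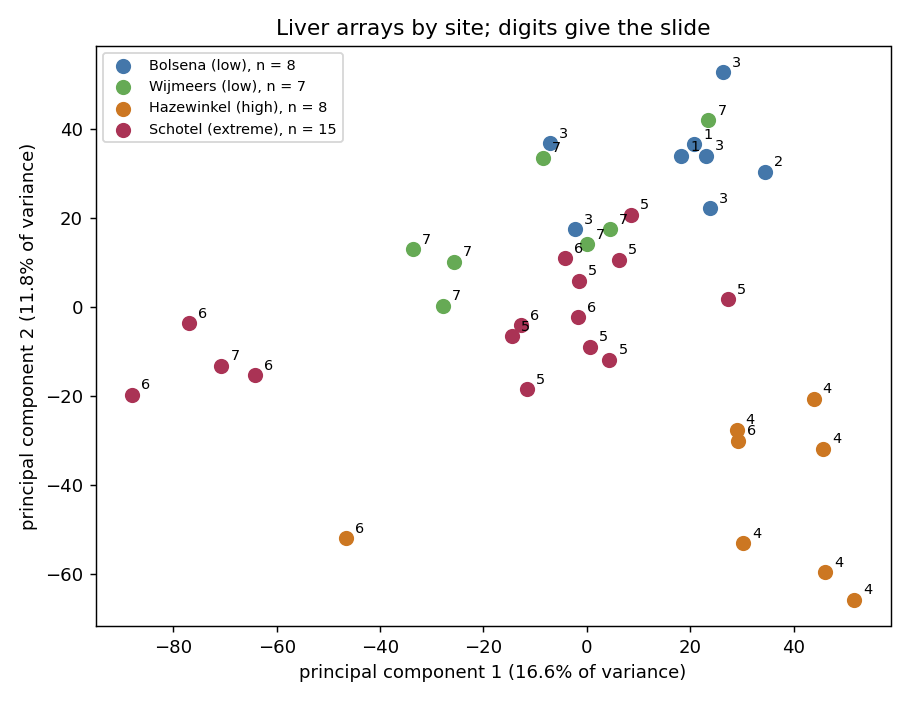
Each point is the array of 1 eel, placed by its scores on principal component 1 (horizontal axis, 16.6% of variance) and 2 (vertical axis, 11.8%), coloured by site, with the slide number beside it. The 8 Hazewinkel arrays lie at -20.6 or below on the second component, on both of their slides, while the 8 Bolsena arrays lie at 17.4 or above.

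Hazewinkel was compared with Wijmeers to set high against low pollution within Belgian ponds. P_eeel_c31183 (60-mer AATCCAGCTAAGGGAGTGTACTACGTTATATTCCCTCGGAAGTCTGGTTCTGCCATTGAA) rose most: its level was 0.88 ± 2.31 (SD, n = 8) in Hazewinkel and -5.46 ± 1.03 (SD, n = 7) in Wijmeers. The difference was 6.33 ± 0.72 log2 units (SE, adjusted p = 7.91e-08), with all 8 Hazewinkel animals above the Wijmeers mean. P_eeel2_rep_c5072 (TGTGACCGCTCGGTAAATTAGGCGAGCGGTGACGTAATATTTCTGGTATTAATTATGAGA) was higher by 4.72 ± 0.73 (SE, adjusted p = 1.6e-05), at -0.17 ± 1.46 (SD, n = 8) against -4.89 ± 1.98 (SD, n = 7). AS_eeel_c5771 fell by 4.44 ± 1.08 (SE, adjusted p = 0.00295), in 7 of 8 Hazewinkel animals. S_eeel_c28632 fell by 3.84 ± 1.29 (SE, adjusted p = 0.0294), in 8 of 8, and was well above background in 1 of 8 Hazewinkel and 5 of 7 Wijmeers livers. Its level varied widely between Wijmeers animals, from -7.47 to 1.79, at -3.33 ± 3.64 (SD, n = 7). In Hazewinkel it was -7.17 ± 1.02 (SD, n = 8). P_eeel_c31183 was well above background in all 8 Hazewinkel livers and in 4 of 7 from Wijmeers. With normexp the differences were smaller, at 3.80 for P_eeel_c31183, 2.39 for P_eeel2_rep_c5072, -2.99 for AS_eeel_c5771 and -1.17 for S_eeel_c28632. The normexp offset of 50, added to every signal, shrinks differences of dim probes by construction, here and in the comparisons below.

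In total, 2074 probes differed between Hazewinkel and Wijmeers, 960 higher and 1114 lower in Hazewinkel, so 46.3% were higher. At least 2-fold differences were seen in 628 higher and 651 lower probes, and at least 4-fold differences in 163 and 57. The split depended on scaling, with 64.6% higher under median centring and 58.9% under normexp background correction, where 975 probes passed and S_eeel_c28632 did not. No slide held arrays of both sites: 600 probes passed with slide as a random block, 21 with slide as a fixed block (median SE of the 2074 probes 0.72 against 0.30, median difference 0.76 against 1.13, with 84.5% of these probes in the same direction) and 3180 with array weights.

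Schotel livers, from the water described as extremely polluted, differed from those of Wijmeers in few probes. Of 9628 probes, 4 passed in limma (1278 at an unadjusted p under 0.05). P_eeel_c49644 (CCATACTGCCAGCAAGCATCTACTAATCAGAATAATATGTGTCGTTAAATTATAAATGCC) was higher in Schotel by 1.37 ± 0.25 (SE, adjusted p = 0.0274), at -0.61 ± 0.66 (SD, n = 15) against -1.98 ± 0.50 (SD, n = 7). P_eeel_c3232 was higher by 1.06 ± 0.21 (SE, adjusted p = 0.0481), and N_eeel_c5972, which was named after its values were seen, by 0.78 ± 0.16 (SE, adjusted p = 0.0481). P_eeel2_c449 fell by 0.97 ± 0.20 (SE, adjusted p = 0.0481), from 2.32 ± 0.42 (SD, n = 7) in Wijmeers to 1.35 ± 0.32 (SD, n = 15) in Schotel. All 15 Schotel animals lay on the called side of the Wijmeers mean for each of these 4 probes.

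P_eeel_c3232, N_eeel_c5972 and P_eeel2_c449 also passed, in the same direction, between Hazewinkel and Wijmeers (adjusted p = 8.57e-07, 2.09e-05 and 0.000588), while P_eeel_c49644 did not pass there (adjusted p = 0.0782). The median absolute difference of the 4 probes was 1.01 log2 units, and 2 of them rose at least 2-fold. The 4 calls were lost, with 0 passing, under median centring (1146 at an unadjusted p under 0.05 in limma), normexp (787) and slide as a random block (614). They were also lost without the filter on dim probes (1498), with only the arrays compared (1360) and without arrays whose 75th percentile was under 200 (1182). The differences of P_eeel_c49644, P_eeel_c3232, N_eeel_c5972 and P_eeel2_c449 were 1.33, 1.02, 0.74 and -1.01 with median centring and 0.81, 0.88, 0.78 and -0.82 with normexp. With slide as a fixed block 10 probes passed, of which 0 were among these 4, with array weights 184 passed, these 4 included, and leaving out 1 array at a time gave 0 to 30. With the fixed block, both differences from Wijmeers (10 and 21 probes) rested on Schotel 15, the only other array of slide 7, which was assumed to vary like the rest although its negative-control SD of 53.7 was the highest of all arrays.

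Schotel and Hazewinkel, the more polluted sites, differed in 2359 probes. P_eeel_c31183 was far lower in Schotel, at -5.10 ± 1.13 (SD, n = 15) against 0.88 ± 2.31 (SD, n = 8), and fell by 5.97 ± 0.61 (SE, adjusted p = 6.1e-09). P_eeel_c25917 (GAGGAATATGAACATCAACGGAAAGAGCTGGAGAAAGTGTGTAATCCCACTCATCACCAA) fell by 4.35 ± 0.65 (SE, adjusted p = 6.22e-06) and was well above background in 3 of 15 Schotel and 8 of 8 Hazewinkel livers. AS_eeel_c5771 was higher in Schotel by 3.69 ± 0.92 (SE, adjusted p = 0.00312), at 1.36 ± 1.44 (SD, n = 15) against -2.33 ± 2.75 (SD, n = 8). P_eeel2_c825 was higher by 2.95 ± 0.28 (SE, adjusted p = 9.94e-10), and was well above background in 13 of 15 Schotel livers but 1 of 8 from Hazewinkel. For each of these 4 probes, all 15 Schotel animals lay on the called side of the Hazewinkel mean. With normexp the differences were -3.87 for P_eeel_c31183, -2.01 for P_eeel_c25917 and 2.24 for AS_eeel_c5771.

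Of the 2359 probes, 1447 were higher and 912 lower in Schotel, or 61.3% higher, with 617 and 448 at least 2-fold apart. Median centring gave 37.6% higher and normexp 46.2%, the latter with 1170 probes passing, and under normexp the difference in P_eeel2_c825 was 0.13 and did not pass. With slide as a fixed block 163 probes passed, and within slide 6, which held 2 Hazewinkel and 6 Schotel arrays, 12 passed. Over the 2359 probes, the median difference in the called direction went from 0.95 to 0.78 with the fixed block and the median SE from 0.26 to 0.44, with 97.3% of probes in the same direction.

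**Figure D3:**
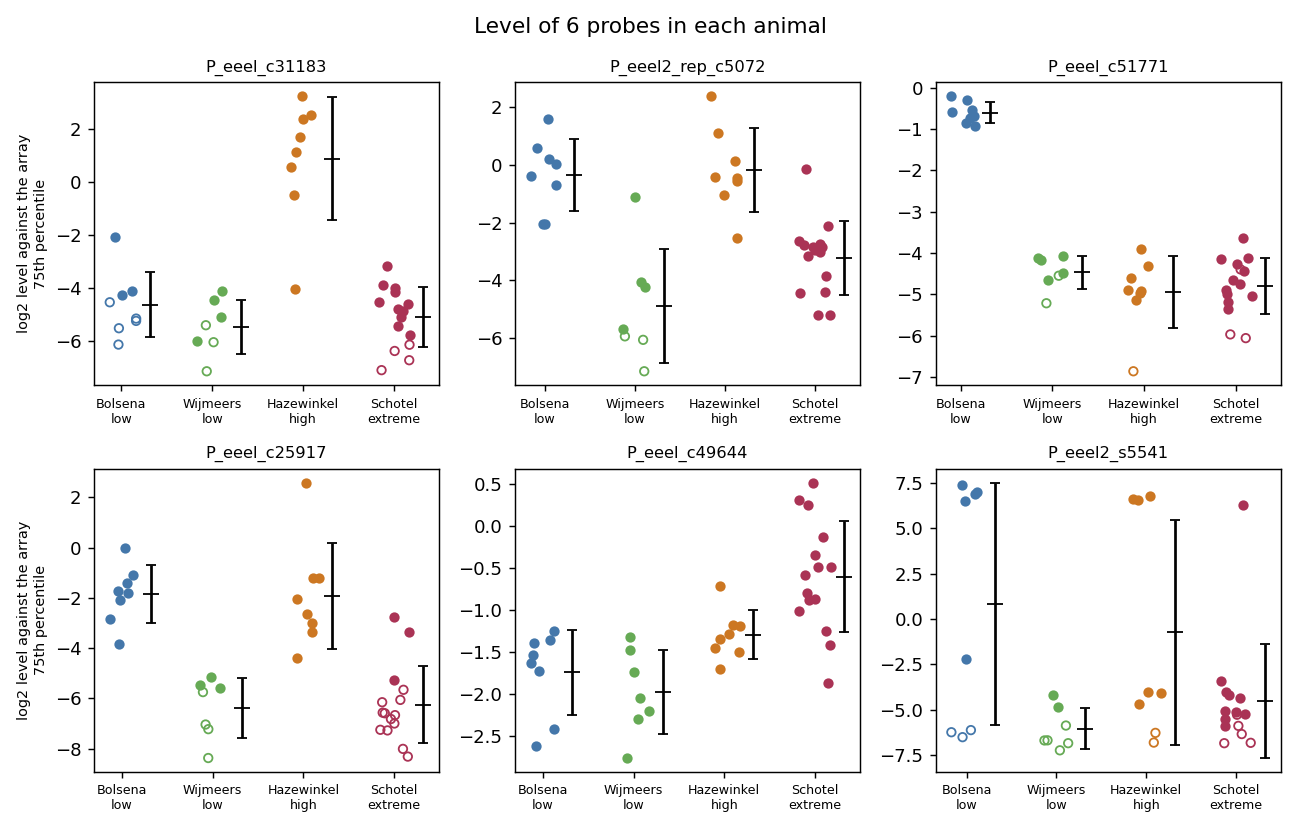
Level of 6 probes in each animal (vertical axes, log2 units against the 75th percentile of the array) at the 4 sites (horizontal axes), with bars for the mean and SD, filled points where the probe was well above background and open points where it was not. P_eeel_c31183 averaged 0.88 in Hazewinkel and -4.62 or less elsewhere, P_eeel_c51771 averaged -0.61 in Bolsena and -4.47 or less elsewhere, and P_eeel2_s5541 fell into a high and a low set of animals.

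Hazewinkel was also compared with Bolsena, the Italian lake of low pollution. P_eeel_c31183 was again higher in Hazewinkel, by 5.50 ± 0.70 (SE, adjusted p = 5.33e-07, 8 of 8 animals above the Bolsena mean). P_eeel_c23702 was higher by 4.60 ± 0.77 (SE, adjusted p = 3.01e-05) and was well above background in 8 of 8 Hazewinkel and 2 of 8 Bolsena livers. P_eeel_c51771 (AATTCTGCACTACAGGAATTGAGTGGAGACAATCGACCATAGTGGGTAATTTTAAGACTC) fell by 4.35 ± 0.31 (SE, adjusted p = 1.21e-12), from -0.61 ± 0.25 (SD, n = 8) in Bolsena to -4.95 ± 0.87 (SD, n = 8), in 8 of 8 animals. P_eeel2_c3000 fell by 4.03 ± 0.68 (SE, adjusted p = 3.47e-05) and was well above background in 2 of 8 Hazewinkel and 8 of 8 Bolsena livers. With normexp the differences were 3.60 for P_eeel_c31183, 2.16 for P_eeel_c23702, -1.89 for P_eeel_c51771 and -0.55 for P_eeel2_c3000.

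In total, 2497 probes differed between Hazewinkel and Bolsena, with 1048 higher and 1449 lower in Hazewinkel, or 42.0% higher. Median centring gave 61.1% higher, normexp left 1343 probes and ended the call for P_eeel2_c3000, and without the filter on dim probes 4947 passed, with 22.4% higher. Every Bolsena array was scanned apart from every Belgian array and no slide held both, and 1330 probes passed with slide as a random block.

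Schotel differed from Bolsena in 2137 probes, 1084 higher and 1053 lower in Schotel. P_eeel_c9599 was higher by 2.73 ± 0.89 (SE, adjusted p = 0.0239) and AS_eeel_rep_c22317 by 2.73 ± 0.61 (SE, adjusted p = 0.00147), each in 14 of 15 Schotel animals. P_eeel_c25917 fell by 4.41 ± 0.65 (SE, adjusted p = 1.45e-05), in 15 of 15 animals, from -1.84 ± 1.15 (SD, n = 8) in Bolsena to -6.25 ± 1.53 (SD, n = 15) in Schotel, where it was well above background in 3 of 15 livers, so most Schotel values lay near the background. P_eeel2_s5541 (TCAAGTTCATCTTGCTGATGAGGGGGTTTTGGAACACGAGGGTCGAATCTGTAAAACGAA) fell by 5.35 ± 1.93 (SE, adjusted p = 0.042), but its level varied widely between animals of 1 site, at 0.83 ± 6.68 (SD, n = 8) in Bolsena and -4.52 ± 3.15 (SD, n = 15) in Schotel. With normexp the differences were 1.26 for AS_eeel_rep_c22317, 2.01 for P_eeel_c9599, -1.60 for P_eeel_c25917 and -4.17 for P_eeel2_s5541. At least 2-fold differences were seen in 458 higher and 422 lower probes. With slide as a random block 968 probes passed, with normexp 1076 (P_eeel_c9599 not among them) and with Schotel arrays of slide 5 only 1150. Without the filter on dim probes 5069 passed, with 24.6% higher against 50.7%.

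Wijmeers and Bolsena, both low in pollution, differed in 461 probes, 200 higher and 261 lower in Wijmeers. No slide or scan run held arrays of both sites. P_eeel_c30098 was higher in Wijmeers by 4.57 ± 1.36 (SE, adjusted p = 0.0437), at -1.13 ± 0.51 (SD, n = 7) against -5.71 ± 2.17 (SD, n = 8). N_eeel_c21610 was higher by 2.96 ± 0.81 (SE, adjusted p = 0.029). In Bolsena these probes were well above background in 1 of 8 and 2 of 8 livers, so most Bolsena values lay near the background, and in Wijmeers in 7 of 7. P_eeel2_rep_c5072 fell by 4.55 ± 0.73 (SE, adjusted p = 0.000207) and P_eeel_c25917 fell by 4.52 ± 0.77 (SE, adjusted p = 0.000586), with Wijmeers values in part near the background, as 4 of 7 and 3 of 7 livers were well above it. All 7 Wijmeers animals lay on the called side of the Bolsena mean for each of the 4 probes. The share of higher probes was 43.4%, but 59.9% with quantile normalization, and with normexp 65 probes passed (27.7% higher), P_eeel_c30098 (1.77), N_eeel_c21610 (1.23) and P_eeel_c25917 (-1.49) not among them, while P_eeel2_rep_c5072 went to -2.07. With slide as a random block 14 passed, all of them lower in Wijmeers, without the filter on dim probes 3433 (12.8% higher), with array weights 1360, and with 1 array left out at a time 214 to 666.

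The mean of both polluted sites differed from the mean of both low-polluted sites in 2149 probes, 986 higher and 1163 lower. The p-values here rest on the spread between animals within sites, not on the spread between waters of a pollution class. P_eeel_c31183 was higher by 2.93 ± 0.47 (SE, adjusted p = 3.08e-05), in 16 of 23 animals of the polluted sites, and P_eeel_c23702 by 2.42 ± 0.52 (SE, adjusted p = 0.000839), in 18 of 23. P_eeel_c51771 fell by 2.34 ± 0.21 (SE, adjusted p = 1.4e-09), in 23 of 23, and P_eeel2_c3000 fell by 2.37 ± 0.46 (SE, adjusted p = 0.000291), in 21 of 23, each counted against the mean of the 2 low-polluted site means. With normexp the differences were 1.77, 1.12, -1.05 and -0.49 for P_eeel_c31183, P_eeel_c23702, P_eeel_c51771 and P_eeel2_c3000. Among the 4 sites, P_eeel_c31183 and P_eeel_c23702 were highest in Hazewinkel, at 0.88 and -0.46, and P_eeel_c51771 and P_eeel2_c3000 were highest in Bolsena, at -0.61 and -2.69. In Wijmeers, P_eeel_c51771 and P_eeel2_c3000 averaged -4.47 and -5.20, also below the references of -2.537 and -3.945. They did not pass in limma between Hazewinkel and Wijmeers (adjusted p = 0.281 and 0.118) or between Schotel and Wijmeers (adjusted p = 0.674 and 0.681). In Schotel the level of P_eeel_c31183 was -5.10 ± 1.13 (SD, n = 15), against -5.46 ± 1.03 (SD, n = 7) in Wijmeers. The share of higher probes was 45.9%, and 60.6% with median centring, while 923 probes passed with slide as a random block and 1121 with normexp, where P_eeel2_c3000 did not pass.

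Comparisons that share no array were set side by side to see whether differences between polluted and low-polluted sites recurred in separate animals. Each comparison was fitted on only its own arrays, so its calls are not those reported above. Hazewinkel against Wijmeers and Schotel against Bolsena shared 126 higher probes, against 94.6 for independent lists (Fisher's exact test, p = 0.000589), and 107 lower probes, against 105.4 (p = 0.87). A further 214 probes were called in opposite directions, a number for which no expected value was computed. The 126 shared higher probes thus cannot be told apart from probes that tend to be called in either direction. No recurrence can be read from their p-value. The correlation of the differences across probes was -0.01, within the range of -0.31 to 0.26 in 100 simulations without effects. For Schotel against Wijmeers and Hazewinkel against Bolsena, 0 probes were shared, since the fit of only the Schotel and Wijmeers arrays called 0 probes in limma (1360 at an unadjusted p under 0.05). The correlation there was 0.31, against a simulated range of -0.32 to 0.29. These comparisons share no array, but slide 6 held arrays of both Hazewinkel and Schotel. The simulations shuffled arrays over slides, so their ranges do not allow for slide, and a recurrence cannot be read from 0.31.

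Hazewinkel and Schotel, each against Wijmeers, shared 2 higher probes and 1 lower probe, against 0.3 and 0.1 for independent lists. Across probes their differences correlated at 0.49, but the shared Wijmeers arrays alone gave 0.60 (0.38 to 0.77) in 100 simulations of unchanged groups. The covariance was 0.178, against 0.0886 in the simulations, a difference of 0.0896. With the Wijmeers arrays split between the comparisons in 35 ways, the mean correlation was 0.22, the mean covariance 0.0975, and the number of shared calls had a median of 0 and a highest value of 3. Simulated unchanged groups shared a median of 0 calls and at most 204.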

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

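The share of simulated changes recovered, the array brightness covariate, the omission of dim arrays, and the fits by slide among Schotel and Hazewinkel arrays were chosen after the counts had been seen.

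Hazewinkel and Schotel, both polluted, differed from each other in 2359 probes. This is also the count for how they differed from Wijmeers, since Wijmeers cancels there. It is the count already given for Schotel against Hazewinkel and no separate test. Slide as the whole cause is argued against by slide 6: of 1941 probes called between the Hazewinkel arrays of slide 4 and the Schotel arrays of slide 5, 89.9% had the same direction between the 2 Hazewinkel and 6 Schotel arrays of slide 6, with a median difference of 0.66 against 0.99, and the true labels ranked 1 of the 28 splits of that slide (highest other 0.47). Among the other splits of that slide, the highest share of probes in the same direction was 76.2%. Array brightness and GC content of the probes are argued against as the whole cause by 3108 probes passing with brightness as a covariate and 2349 after centring within bins of GC content. Part of the difference may still come from slides, since the held-out difference was 0.66 of the first and only 2 Hazewinkel animals carry it, with 72.9% of probes in the called direction for Hazewinkel 1 and 86.3% for Hazewinkel 2. A biological difference between the waters, in pollutants or otherwise, stays among the open explanations and was not tested.

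Schotel, described as extremely polluted, gave 4 probes against Wijmeers. Dim Schotel arrays and a shift between Schotel slides are argued against as what hides a large difference: 0 probes passed in limma without the arrays under 200 (1182 at an unadjusted p under 0.05), and the Schotel arrays of slide 5 alone gave 27 and those of slide 6 alone 0 (1485 at an unadjusted p under 0.05). In simulations, 52.1% of changes of 1 log2 unit and 9.6% of changes of 0.5 units were recovered. Too few animals is thus argued against only as what hides many changes of 1 unit or more. The simulations mixed changes of 0.5, 1 and 2 units over 200 probes and shuffled arrays over slides. They gave 23.6 false calls per run. Unequal array quality stays open, since 72 probes passed with brightness as a covariate and 184 with array weights. Whether eels of the 2 waters differ by small amounts in many transcripts cannot be read from these counts.

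Wijmeers and Bolsena, both low in pollution, differed in 461 probes. Arrays of a single site on different slides also differed. Within Schotel, 236 probes passed between slide 5 (8 arrays) and slide 6 (6 arrays). Within Bolsena, 23 passed between slides 1 and 2 (3 arrays) and slide 3 (5 arrays). Within Hazewinkel, 3 passed between slide 4 (6 arrays) and slide 6 (2 arrays). With unlike numbers of arrays, these splits differ in power. Slide 6 held Schotel 2, 6 and 7, the dimmest arrays of all (75th percentiles 139, 156 and 125), so the 236 mixes brightness with slide. Slide-to-slide differences of the size seen within a site cannot be told apart from the site in part of the 461. Scan period cannot be told apart from the site either, since Bolsena and Belgian arrays shared 0 scan runs. Distance between the Italian and Belgian waters is a further open explanation, and was not tested.

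In each comparison, 1 of 100 splits of the arrays into groups of the same sizes, the true one, gave as many probes. Chance in the placing of single arrays is argued against on that basis for all comparisons except Schotel against Wijmeers, where the margin was 1 probe. With 100 splits, 1 is the lowest number possible, since the true split counts. For the polluted against the low-polluted sites, animals were moved over all 4 sites. Those splits therefore cannot exclude chance in which sites fell in each class. The splits ignored slide, so they exclude no slide effect: 21 probes passed for Hazewinkel against Wijmeers with slide as a fixed block, and 14 for Wijmeers against Bolsena with slide as a random block. The true counts and the highest of the other 99 splits were 2074 and 257 for Hazewinkel against Wijmeers, 4 and 3 for Schotel against Wijmeers, 2359 and 209 for Schotel against Hazewinkel, 2497 and 1076 for Hazewinkel against Bolsena, 2137 and 2 for Schotel against Bolsena, 461 and 381 for Wijmeers against Bolsena, and 2149 and 6 for the polluted against the low-polluted sites. The split with 1076 probes differed from the true labels in 2 of 16 arrays and that with 381 in 4 of 15, so both lay near the true grouping.

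Single animals stood far from the others of their site in 8 of 60 sets of values, where chance gives about 1 in 20. The sets were 18 named probes and 2 array measures at each of 3 sites, and Schotel, with more than 10 animals, was not tested. In Bolsena, animal 4 was highest for S_eeel_c28632 at -2.84 (next -5.47) and for P_eeel_c30098 at -0.45 (next -5.54). Bolsena animal 2 was lowest for AS_eeel_rep_c22317, at -6.48 (next -4.69). On the array of Bolsena animal 3, 48.92% of probes were well above background, the lowest share of the site (next 54.58%). In Hazewinkel, animal 5 was highest for S_eeel_c28632, at -4.70 (next -7.10), and its array had the lowest share of probes well above background, 57.71% (next 63.72%). Hazewinkel animal 3 was highest for P_eeel_c25917, at 2.58 (next -1.21). Hazewinkel animal 1 was lowest for P_eeel_c51771, at -6.86 (next -5.13).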

How the results depend on the processing

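The fits by brightness, by dim arrays, by Schotel slide, within slides 6 and 7, and with slide as a random block among Belgian sites were chosen after the data were seen. Counts for Hazewinkel against Wijmeers, Schotel against Hazewinkel, Hazewinkel against Bolsena, Schotel against Bolsena and the polluted against the low-polluted sites stayed within 1.5 times the reported ones under quantile normalization, median centring, the authors' values, the stricter filter, fits of only the arrays compared (not run for the polluted against the low-polluted sites), and a trended and robust eBayes step. The cause of the changes below was not tested unless stated. With normexp, 975 probes passed for Hazewinkel against Wijmeers, 0 for Schotel against Wijmeers, 1170 for Schotel against Hazewinkel, 1343 and 1076 for Hazewinkel and Schotel against Bolsena, 65 for Wijmeers against Bolsena and 1121 for the polluted sites. Without the filter on dim probes, 4947, 5069 and 3433 passed for Hazewinkel, Schotel and Wijmeers against Bolsena, and 0 for Schotel against Wijmeers. Among 1798 probes above background nowhere, the median signal was 3.10 to 11.7 on Bolsena arrays and 1.68 to 4.31 on Belgian ones, so the floor reached higher in Bolsena, although the ranges overlapped. With slide as a fixed block, 21, 10 and 163 passed for Hazewinkel and Schotel against Wijmeers and Schotel against Hazewinkel, and as a random block 600, 0 and 1215. The random block gave 1330, 968 and 14 for Hazewinkel, Schotel and Wijmeers against Bolsena and 923 for the polluted sites. Array weights gave 3180 for Hazewinkel against Wijmeers, 184 for Schotel against Wijmeers and 1360 for Wijmeers against Bolsena. Without arrays under 200 the latter 2 counts were 0 and 697, and with brightness as a covariate 72 and 793. Schotel arrays of slide 5 only gave 27, 1531 and 1150 against Wijmeers, Hazewinkel and Bolsena, and those of slide 6 only 0 against Wijmeers. Slide 6 alone gave 12 for Schotel against Hazewinkel, with fewer arrays, and slide 7 alone 2 for Schotel against Wijmeers, from 1 Schotel array assumed to vary like those of Wijmeers. For Schotel against Wijmeers, 0 also passed with median centring and with only the arrays compared, and limma's unadjusted p was under 0.05 for 614 to 1498 probes in the fits with 0 calls.

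Leaving out 1 array at a time gave 1690 to 2389 probes for Hazewinkel against Wijmeers, 0 to 30 for Schotel against Wijmeers, 1845 to 2883 for Schotel against Hazewinkel, 2144 to 2551 and 1797 to 2269 for Hazewinkel and Schotel against Bolsena, 214 to 666 for Wijmeers against Bolsena and 1843 to 2218 for the polluted sites. For Wijmeers against Bolsena, the count was 263 without Bolsena 3, and 280, 258, 282, 251 and 214 without Wijmeers 2, 3, 5, 6 and 7. For Schotel against Wijmeers it was 0 without Schotel 1 or 6 or Wijmeers 2, 3 or 6, 1 without Schotel 4, 7, 8, 11, 13 or 14 or Wijmeers 1, 2 without Wijmeers 5, 7 without Schotel 3 or 15, 8 without Schotel 9, 10 without Schotel 10, 15 without Wijmeers 7 and 30 without Wijmeers 4.

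Median centring moved the median difference over all tested probes from -0.06 to 0.09 for Hazewinkel against Wijmeers, 0.07 to -0.13 for Schotel against Hazewinkel and -0.06 to 0.11 for Hazewinkel against Bolsena. Of 116 values of named probes under scaling, background and filter alternatives, 96 passed in the same direction, 20 had the same direction and did not pass, and 0 turned. The values cover 18 probes, some of them in several comparisons. A change of filter leaves the difference of a probe as it was, so the values under filter alternatives could not turn. The normexp setting adds an offset of 50 to every signal, which by construction shrinks the differences of dim probes. P_eeel2_c825 went from 2.95 to 0.13 with normexp, and the part of the offset in this was not tested. No paired analysis was possible because replicate numbers only name animals.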

Other observations

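The probe classes, the probes with a gap between animals and all tests in this part were chosen after the data were seen.

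Probes whose names begin with S leaned higher in the eels of each Belgian site than in those from Bolsena, most clearly for Schotel and Hazewinkel. Between Schotel and Bolsena, 242 of these probes were higher in Schotel and 38 lower, or 86.4% higher, against 42.0% for P and N probes matched on level (Fisher's exact test against all P and N calls, adjusted p = 6.65e-45 over 12 tests, with probes taken as independent). Over all S probes tested, the median difference was 0.28 log2 units, against -0.03 for P and N probes. Between Schotel and Bolsena the share was 88.9% with quantile normalization, 86.5% with median centring, 87.7% with normexp and, of 133 calls, 88.0% with slide as a random block. The share was 73.8% between Hazewinkel and Bolsena, and 79.1% of 158 calls with the random block. Between Wijmeers and Bolsena it was 69.1% of 55 calls, against 41.0% for matched probes (adjusted p = 8.85e-05). There it was 79.1% with quantile normalization, 71.4% with median centring and 42.9% of 7 calls with normexp, against 56.8%, 47.9% and 25.9% for P and N probes. With the random block 0 S probes passed there in limma, while the median difference over all S probes was 0.10, against -0.04 for P and N probes (0.13 and -0.04 without a block). Between Hazewinkel and Wijmeers, which shared no slide, 65.2% of 230 S calls were higher in Hazewinkel, against 46.9% for matched probes (adjusted p = 2.1e-09), with 85 S calls left under the random block (74.1% higher, against 48.4% for P and N probes) and 4 under the fixed block. The median difference there over all S probes was 0.05, against -0.08 for P and N probes, and with the fixed block, which rested on 1 Schotel array, 0.36 against -0.10. Between Schotel and Hazewinkel, which shared slide 6, the S share was 57.1%, against 57.8% for matched probes (adjusted p = 0.456). The AS probes were higher in Schotel than in Bolsena in 79.6% of 147 calls, against 47.1% for matched P and N probes, and in 44.2% of 43 calls between Wijmeers and Bolsena, against 42.1%. Between Schotel and Hazewinkel 79.5% of 190 AS calls were higher, against 64.4% for matched probes. There the AS share was 58.1% with median centring, against 36.1% for P and N probes, and 56.6% of 53 calls with normexp, against 45.4%. With slide as a fixed block, 4 of 10 AS calls were higher there, against 56.7% of P and N calls. Over all AS probes the median difference there was 0.29, against 0.05 for P and N probes, and 0.26 against 0.05 with the fixed block, but with normexp it was -0.15 for both, so the shift was not seen with normexp. All Bolsena arrays were scanned apart from the Belgian ones, so scan and site cannot be told apart in the comparisons with Bolsena.

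For 1390 contigs the array holds both an S and an AS probe, and both were tested for 580. Within sites, the levels of the 2 probes of a contig correlated with a median of 0.37 across animals, against 0.09 for an S probe and an AS probe of another contig. Of 57 contigs with both probes called between Schotel and Hazewinkel, 48 went in the same direction, as did 43 of 46 between Schotel and Bolsena and 36 of 38 between Hazewinkel and Wijmeers. From the shares of S and AS probes that rose among these contigs, 34.2, 34.8 and 18.9 would agree if their directions were unrelated.

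The levels of P_eeel2_s5541 fell into a high and a low set of animals. This probe was well above background in 5 of 8 Bolsena, 6 of 8 Hazewinkel, 10 of 15 Schotel and 2 of 7 Wijmeers livers. Part of the low set thus had signal above background. In 8 of 38 eels its level lay between 6.29 and 7.36, and in the other 30 between -7.25 and -2.23, a gap of 8.52 log2 units. The 8 eels were 4 from Bolsena, 3 from Hazewinkel, 1 from Schotel and 0 from Wijmeers (Fisher's exact test over sites, p = 0.0283, adjusted p = 0.0566 over 2 probes). They lay on slides 1, 3, 4, 5 and 6, and the highest correlation of another probe with it was 0.75. The call between Schotel and Bolsena therefore rests on how many animals carry the high level, not on a shift shared by all animals. Of 9628 probes, 2 had a gap of at least 5 units with at least 3 animals on each side. The second, P_eeel_c8212, was high in 33 of 38 eels, between 1.73 and 6.67, and at -6.06 or below in the other 5, of which 1 came from Bolsena, 2 from Schotel and 2 from Wijmeers (p = 0.437).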
